A study of Drosophila melanogaster with 19 samples.

How the data were processed

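AdMTase-seq was carried out on nuclei of S2-DRSC cells (spelled S2-DSRC in the labels), a hemocyte-like embryonic cell line of Drosophila melanogaster. Per the labels' protocols, nuclei were incubated for 20 min at 37 °C with an m6A methyltransferase, an enzyme that methylates adenines in DNA it can reach. Short DNA fragments carrying m6A were recovered with an antibody and made into Illumina libraries. The series used here holds 19 libraries in 17 groups. There were 17 treated libraries from 5 enzymes, namely Hia5 at 200, 60, 20, 6, 2 and 0.6 U, EcoGII and Btr192IV at 6, 2 and 0.6 U, EcoGI at 2 and 0.6 U, and Hin1523 at 2 U. The controls were 1 immunoprecipitation from untreated cells and 1 DNA input. Only 2 groups, Hia5 at 2 U and at 6 U, held 2 libraries, and the other 15 groups held 1 library each. Nothing in the labels states that the replicates came from separate cultures. The p-values of tests that compare libraries therefore measure only the spread between these libraries, which may be technical. Those from random placement of peaks and from Fisher's exact test on gene lists do not measure that spread.

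The authors deposited 1 peak list per library, called on each library separately, with an FDR of 5% per the file names. Each peak came with its start, end and height in the authors' tag-density signal. The submitters' processing notes name BWA 0.7.12, SAMtools 1.2 and the builds GRCh38 and dm6, of which dm6 (release 6 of the fly assembly) is the fly build. The peak caller, any subtraction of input and any filters are not given in the sources used here. The deposited signal heights in every library were whole multiples of 1 step, with a tolerance of 0.05 of a step. The inverse of that step was taken as the relative depth of the library. It ran from 7.28 to 25.5 over the treated libraries, with a median of 9.28, and was 11.3 in the untreated library and 0.673 in the input. Sequencing totals are not given in the sources used here, so the relative depth sets libraries against each other and gives no number of reads. Heights are the authors' values and were used only to rank or filter peaks within a list.

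Positions were set against a table of 17807 genes on 7 chromosomes of the same release 6 assembly, of which 13946 were protein-coding. That table gives each gene's start and end without strand, exons or sequence. The planned windows around 5' ends were therefore replaced by windows of 500 bp on either side of both ends of each gene, called gene ends below. A peak that touched such a window by at least 1 bp was counted at a gene end, any other peak inside a gene was counted in a gene body, and the rest were intergenic. Promoters inside long genes are not covered by these windows, and 3' ends are. Motifs, GC content, exons and introns were not analysed here. No peak lay on unplaced sequence.

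Libraries were split into a first run of 7 and a second run of 12 by their library numbers, which is an inference from the labels. The replicate number of Hia5 at 2 U and 6 U follows that run. The dose trend was tested over the 8 Hia5 libraries with Pearson's r and Spearman's rho against log10 dose, by exact two-sided permutation of pairings, with Benjamini-Hochberg adjustment over 3 measures. Correlations within a run were planned and then left out, since the runs hold 5 and 3 Hia5 libraries and fewer than 6 were not correlated; the values within each run are given instead. Hia5 at 6 U and 2 U were compared by an exact two-sided permutation test. Hia5 at 0.6 to 6 U (5 libraries) was compared with EcoGII, Btr192IV and EcoGI by exact two-sided permutation tests, adjusted over 6 comparisons, with doses pooled. A comparison at shared doses, with libraries permuted within doses, was added after seeing the data. Similarity of libraries was the Jaccard index of covered bases, tested by 100000 permutations of the labels, one-sided, or by all permutations with fewer than 10 libraries. Overlaps with control peaks and gene ends were set against 100 random placements of the peaks on the same chromosomes, one-sided, where the smallest possible p is 0.0099. Shares of peaks carry 95% Wilson intervals. These cover counting error only, since neighbouring peaks are not independent.

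Hia5 reproducible sites were merged peaks of the 4 libraries at 2 U and 6 U in which each of the 4 had a peak. Sites that overlapped a control peak were counted apart. Fixed gene lists (17) were compared with all other genes of the same biotype by Fisher's exact test, two-sided, adjusted over the lists. They covered hemocyte identity, innate immune signalling, heat shock, cytoplasmic ribosomal proteins, proteasome, glycolysis and cytoskeleton, cell cycle, chromatin and insulator factors, dosage compensation, ecdysone response, Hox and segmentation genes, neuronal, muscle and germline markers, chemoreceptors, the histone repeat cluster and tRNA genes. The tRNA genes were compared with all other genes. In the dosage compensation list 7 of 9 written names matched a gene, since both roX genes were written under old and current symbols, and 10 of 11 germline names matched. The size of a list's difference was changed, after the values were seen, from log2 odds to percentage points, because the odds with an added constant gave lists without any member a positive sign; the p-values were unaffected. Genes are not replicates, so these tests describe the sites of these libraries.

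The genes named were chosen by a rule set before the data were examined. It took 2 to 4 members of each list with at most 14 genes as examples, those with peaks in the most and the fewest treated libraries. It also took the 10 protein-coding genes with the highest reproducible sites outside control peaks, ranked by the mean height percentile over the 4 libraries. For each enzyme against Hia5 it took up to 5 genes per direction with a gene-end peak in all libraries of one side and none of the other, sorted by covered bases. The same sort gave 5 genes per direction for Hia5 200 U against 2 U, and 10 genes for the untreated library. Named outside this rule, after their values were seen, were further list members with a reproducible site or with no peak in any treated library, and the genes at the examples of dense runs. Some genes that the rule took for the untreated library are not reported here.

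Alternatives fixed before the data were examined were the peaks above the median height of each list, peaks under 150 bp apart merged, peaks in controls left out, chromosome Y left out, covered bases in place of peak numbers, windows of 200 and 1000 bp, 50% overlap, peak midpoints within 75 bp, single runs, and each library or enzyme left out. Lists of equal length (the 772 highest peaks, the length of the shortest treated list) were planned for the similarity of enzymes and added after seeing the data for the dose trend and the comparison of enzymes with Hia5. Also added were random placement between 5 and 50 kb from each peak, gene lists set against Hia5 2 U sites or Hia5 0.6 U peaks, and all results without dense runs. A dense run is a stretch of 6 or more peaks with starts at most 3 kb apart. The computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. Overlaps of the 772 Hia5 60 U peaks with Hia5 20 U peaks and randomly placed input peaks were checked at several overlap settings. The 2316 comparisons differed from a plain loop in 0 cases. On simulated data, the gene-end share of 2856 peaks placed as in Hia5 6 U replicate 1 was off by at most 1.02 percentage points. With a background like that of the Hia5 reproducible sites, an unadjusted p under 0.05 was reached by 84 of 100 lists of 12 genes when 30% of members had a site, by 43 of 100 at 10%, and by 13 of 300 lists without a difference.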

Results

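The libraries compared which parts of the S2-DRSC cell genome could be methylated, by which enzyme and at which dose. The deposited lists held 82060 peaks in all. Treated libraries held between 772 peaks (Hia5 60 U) and 13395 peaks (EcoGII 6 U), with a median of 3692, and covered between 131 and 2883 kb. The median peak width of a library ran from 130 to 216 bp. The untreated library held 1974 peaks over 373 kb and the DNA input held 32 peaks over 4.16 kb. Most groups had no replicate, so their values carry no error between samples.

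The background measured in untreated cells lay mostly away from gene ends. Of the untreated peaks, 40.4% were intergenic and 45.7% lay in gene bodies, below the random median of 53.7% (one-sided permutation p = 0.0099, from random placement), and 40.3% lay in dense runs. Where untreated peaks did reach gene ends, the 10 protein-coding genes with the most bases under untreated peaks at their ends included Nubpl, which has a role in building mitochondrial complex I, with 1145 covered bases, Slmap with 1093, CG43149 with 979, CG43968 with 918 and Rev1, a translesion DNA polymerase, with 815. Others among them were CG7791, the ribosomal protein gene RpL21, and Obp99c, an odorant-binding protein gene. Of 17 treated libraries, 14 also had a gene-end peak at Rev1, 13 at CG43149 and at CG7791, and 12 at Slmap. The number was 4 for Obp99c, 3 for Nubpl, and 2 for CG43968 and for RpL21. In all, 182 protein-coding genes had an untreated peak at a gene end. Of the 32 input peaks, 21 lay on X, and 19 of those 21 were overlapped by a peak in all 17 treated libraries.

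The share of treated peaks that overlapped an untreated peak ran from 5.87% (Hia5 0.6 U) to 44.8% (Hia5 60 U), with a median of 15.9%. It was 17.6% at Hia5 200 U, where random placement gave a median of 0.518%, and of 2.13% with peaks moved by at most 50 kb. Overlap with the untreated library and with the input was above random placement in 17 of 17 treated libraries (one-sided permutation p = 0.0099 each, from random placement and the smallest possible). Overlap with input peaks took 0.231% to 4.02% of the treated peaks.

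Peaks gathered at gene ends in most treated libraries. At Hia5 0.6 U 48.9% of peaks lay within 500 bp of a gene end (95% interval 47.8 to 50.0), against a random median of 20.6%. In EcoGII the share was 45.4% at 0.6 U and 45.3% at 2 U, in Hin1523 41.1% at 2 U, and in EcoGI 36.7% at 0.6 U and 34.6% at 2 U. It was 28.8% in EcoGII at 6 U, and in Btr192IV it was 34.7% at 0.6 U, 31.8% at 2 U and 22.3% at 6 U. In the untreated library it was 13.8% (12.4 to 15.4), below the random median of 19.9%, although with peaks moved by at most 50 kb the median was 14.8% (one-sided permutation p = 0.0891), and in the input it was 25.0% of 32 peaks (13.3 to 42.1). The gene-end share was above random placement in 15 of 17 treated libraries. The exceptions at gene ends were Hia5 200 U, with 18.5% against a random median of 20.3%, and Hia5 60 U, with 19.04% against 19.7% (one-sided permutation p = 0.772). The Hia5 200 U share lay below the lowest random placement, 18.7% (one-sided permutation p = 0.0099 for a lower share). That p is the smallest possible, and with 1 library at it the test cannot pass after adjustment over the 17 libraries. For Hia5 200 U with peaks moved by at most 50 kb it was 0.099 (one-sided permutation). With peaks moved by at most 50 kb, an alternative chosen after seeing the data, Hia5 60 U exceeded its random median of 17.03% and 16 of 17 libraries were above random.

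Across the Hia5 dose series, gene ends took a smaller share of the peaks as the dose rose. The share was 48.9% at 0.6 U, 40.4% ± 1.85 at 2 U (SD, n = 2), 28.4% ± 1.11 at 6 U (SD, n = 2), 22.9% at 20 U, 19.04% at 60 U and 18.5% at 200 U. Intergenic peaks took 9.93% of the list at 0.6 U, 35.5% at 60 U and 29.2% at 200 U. Over the 8 libraries the gene-end share fell with log10 dose (r = -0.943, exact two-sided permutation p = 0.000694, adjusted p = 0.00208; rho = -0.988, permutation p = 0.000198). Without 200 U and 60 U r was -0.980, and without 200 U and 0.6 U it was -0.953.

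Within the first library run the gene-end share went from 41.7% at 2 U through 29.2% at 6 U, 22.9% at 20 U and 19.04% at 60 U to 18.5% at 200 U. Within the second run it went from 48.9% at 0.6 U through 39.1% at 2 U to 27.6% at 6 U. In lists of equal length (the 772 highest peaks, chosen after seeing the data) the shares were much closer at low dose: 32.0% at 0.6 U, 34.5% and 31.2% in the 2 U replicates, 32.0% and 30.7% in the 6 U replicates, 29.0% at 20 U, and 19.04% both at 60 U and at 200 U. The correlation with dose in those lists was -0.888 (exact permutation p = 0.00278).

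**Figure D1:**
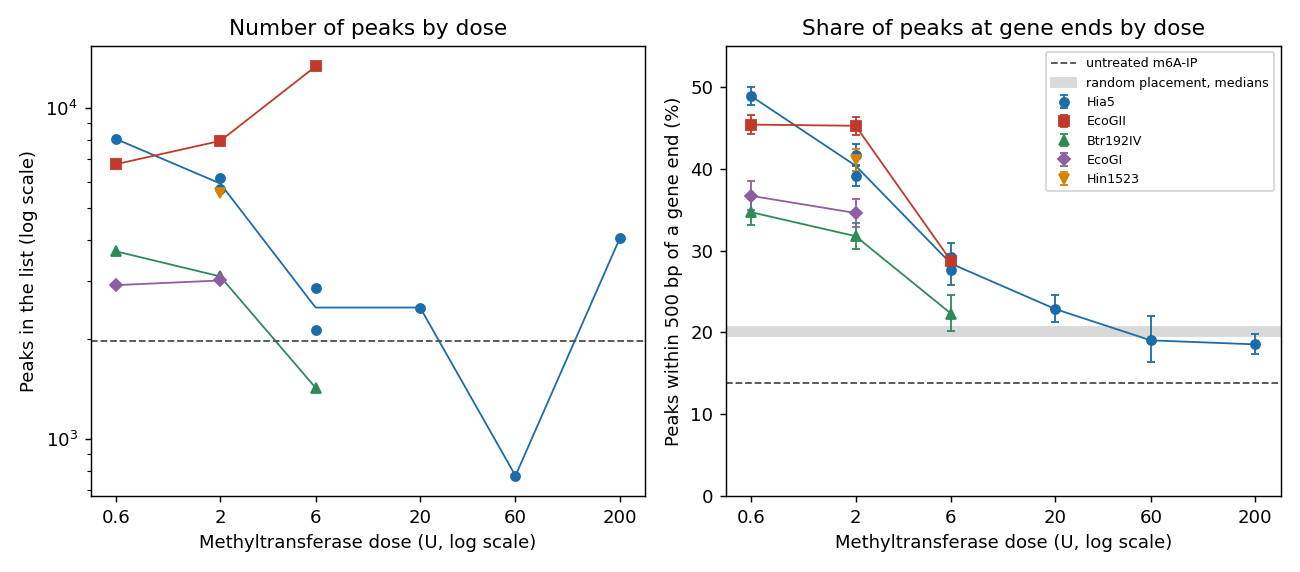
Left, number of peaks in each list (log scale) against methyltransferase dose in U (log scale); right, percent of peaks within 500 bp of a gene end against dose. Points are libraries, lines join the means of each enzyme, bars are 95% Wilson intervals, the dashed line is the untreated library and the grey band spans the medians of random placements. Hia5 falls from 48.9% at 0.6 U to 18.5% at 200 U, and EcoGII 6 U stands highest in number with 13395 peaks.

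The number of Hia5 peaks was 8080 at 0.6 U, 5680 and 6161 at 2 U, 2856 and 2132 at 6 U, 2494 at 20 U, 772 at 60 U and 4054 at 200 U. Its correlation with dose did not pass the test (r = -0.623, exact permutation p = 0.0967, adjusted p = 0.0967; rho = -0.711, permutation p = 0.0562). The 200 U library decided this: without it r was -0.947 (exact permutation, adjusted p = 0.00159). The share of peaks that overlapped untreated peaks rose with dose in rank only before adjustment (rho = 0.747, exact permutation p = 0.0397, adjusted p = 0.0562; r = 0.650, p = 0.0746, adjusted p = 0.0967), and without 200 U r was 0.955 (exact permutation, adjusted p = 0.00119). The 4054 peaks at 200 U included 1724 in dense runs. Without dense runs, an alternative chosen after seeing the data, both correlations passed (r = -0.754 and r = 0.704, exact permutation, adjusted p = 0.0439 each). In lists of equal length the overlap with untreated peaks passed as well (r = 0.916, exact permutation, adjusted p = 0.00278).

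At 6 U each replicate of Hia5 held fewer peaks than its counterpart at 2 U. Relative depth was 11.9 at 6 U and 12.1 at 2 U in replicate 1, but 7.89 and 11.8 in replicate 2. The mean log2 number of peaks was 11.27 ± 0.30 at 6 U and 12.53 ± 0.08 at 2 U (SD, n = 2 each), a difference of -1.26, and the gene-end share fell by 11.97 percentage points. The exact two-sided permutation p was 0.333 for both, the smallest this test can give with 2 libraries against 2, so it cannot pass; no model-based test was run. In the full lists both were larger than the spread between replicates: -0.99 and -1.53 log2 units for peaks, and -12.5 and -11.4 points for gene ends. In lists of equal length the gene-end shares were 32.0% and 30.7% at 6 U, and 34.5% and 31.2% at 2 U. These ranges overlap, so the gene-end difference lay within the spread between replicates there.

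Hia5 peaks lay at the ends of 1725 protein-coding genes in both 2 U libraries and of 543 genes (3.89%) at 200 U, so the shorter list limits how many can be shared. A gene-end peak was present in both 2 U libraries and absent at 200 U for 1605 protein-coding genes, present at 200 U and absent from both 2 U libraries for 317, and present in all 3 libraries for 120. The genes with the most covered bases at 2 U only were hry (hairy, a pair-rule repressor) with a mean of 894 bases per library, Rev1 with 837, the nucleic acid-binding protein gene CNBP with 802, exu, needed for bicoid mRNA localisation, with 791, and CHKov1 with 753. Of these, hry, Rev1 and CNBP also had an untreated peak at a gene end. At 200 U only they were CG6592 with 1221 covered bases, its neighbour CG10472 with 1129, CG14383 with 1108, CG14642 with 1091 and Neurl4 with 999. Each of these 5 genes had at least 4 of its 200 U peaks in a dense run, and in 2 U replicate 1 so did Rev1 with 6 and exu with 4. A single library at 200 U leaves this comparison without a test.

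Sites shared by the Hia5 libraries at 2 U and 6 U were ranked only where they reached the end of a protein-coding gene. Among these, the highest site outside control peaks was at ap (apterous, a LIM-homeodomain factor of dorsal wing fate). Next came sty (sprouty, an inhibitor of receptor tyrosine kinase signalling), kay (the fly Fos), Paics (purine synthesis), Reg-2 and cbt (cabut, a zinc finger factor). They were followed by zfh1 (a zinc finger homeodomain factor of mesoderm and hemocytes), ca and ncd (a minus-end kinesin) at 1 shared site, and Uba1 (the ubiquitin-activating enzyme). The mean height percentile of all these genes within the 4 lists ran from 99.1 for ap to 93.0 for Uba1. Gene-end peaks were present at ap in 16 of 17 treated libraries, at sty, kay and Uba1 in 15, at Paics, Reg-2 and cbt in 14, and at zfh1, ca and ncd in 13. The count at ap depends on the 500 bp window, since each treated library had a peak that overlapped the ap site. The peaks there in Btr192IV 2 U (5726781 to 5727000) and EcoGII 2 U (5726721 to 5726980) ended short of the window. Reg-2 also had an untreated peak at a gene end.

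The ap site spans positions 5726761 to 5727280 on 2R (dm6), at the right end of the gene, which runs from 5706202 to 5727525. The sty site lies on 3L from 3400701 to 3401020, just left of the gene's start at 3401153, and the kay site on 3R from 29765301 to 29765660, left of its start at 29765995. Neither the untreated library nor the input had a peak in the region plotted around the ap site, 5716761 to 5737280. The input held only 32 peaks in all, at a relative depth of 0.673, so its empty region says little.

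**Figure D2:**
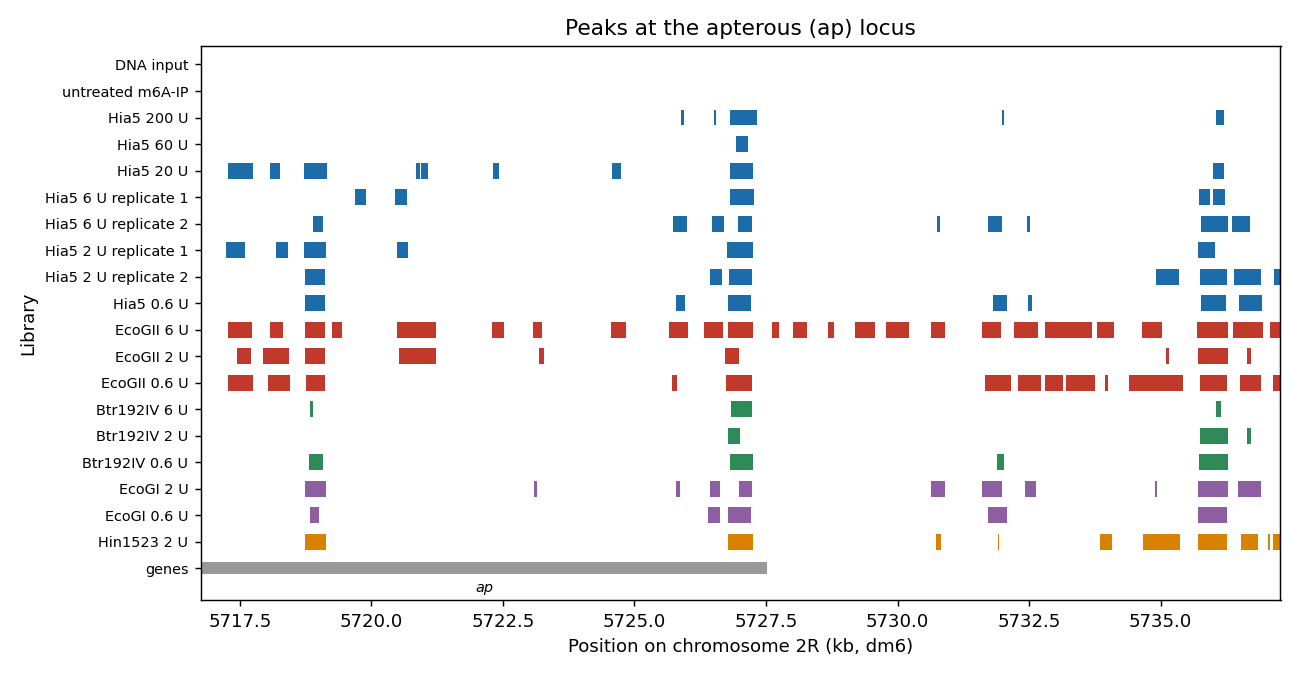
Peaks of each library (rows) along chromosome 2R (kb, dm6) around the reproducible site at ap; coloured bars are peaks from start to end, the grey bar is the gene. Treated libraries share peaks near position 5726761 to 5727280, and the rows of the untreated library and the input are empty. The input held only 32 peaks in all.

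There were 1025 reproducible sites, of which 253 overlapped a control peak (252 an untreated peak, 29 an input peak). Among the 772 others, 331 (42.9%) reached a gene end, against a random median of 22.4% and a highest random value of 26.0%. They reached 411 genes, 333 of them protein-coding. Without 6 U replicate 2, the shortest of the 4 lists, there were 1665 reproducible sites in place of 1025. At 2 U, 65.7% of replicate 1 peaks overlapped replicate 2 and 61.5% the other way (Jaccard index 0.388; random medians 1.80% and 1.62%). At 6 U the shares were 44.4% and 59.7% (Jaccard index 0.281; random medians 0.525% and 0.704%).

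Genes of the Hox and segmentation list, known targets of Polycomb repression, had reproducible Hia5 sites more often than other genes. Of its 14 members, 5 had one, which is 35.7% against 2.35% of other protein-coding genes (adjusted p = 0.000215, Fisher's exact test). They were abd-A and en (engrailed), each with a gene-end peak in 15 of 17 treated libraries, vg (vestigial, a wing regulator) in 14, and Dfd and Dll (Distal-less, a limb regulator) in 13. The sites lay on 3R at 16830081 to 16830340 (abd-A) and 6791501 to 6791840 (Dfd), and on 2R at 11527821 to 11528520 (en), 12884370 to 12884620 (vg) and 24814561 to 24814880 (Dll). Dfd also had an untreated peak at a gene end. The Hox genes Abd-B, Antp and Ubx, and ftz and inv, had no gene-end peak in any treated library. Hemocyte genes came next: 3 of 12 had a site (25.0%, adjusted p = 0.0215, Fisher's exact test), namely zfh1 and the neighbours Col4a1 and vkg, which encode the collagen IV chains. The innate immune list, with 2 of 12, did not pass (adjusted p = 0.136, Fisher's exact test), so the hemocyte call rests on each of its 3 genes. Col4a1 also had an untreated peak at a gene end. With gene-end windows of 200 bp the hemocyte list no longer passed (adjusted p = 0.0686, Fisher's exact test), and neither 6 U library had a single peak at a vkg gene end, although the merged site reached it. The hemocyte genes eater, Hml, NimC1, Sr-CI and ush had no gene-end peak in any treated library.

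The other 15 lists did not pass after adjustment. Innate immune genes had 2 of 12 members with a site (imd and Tl, the Toll receptor gene; p = 0.0320, adjusted p = 0.136, Fisher's exact test). With gene-end windows of 1000 bp the innate immune list passed, with 3 of 12 (25.0%) against 3.37% of other genes (adjusted p = 0.0382, Fisher's exact test). The glycolysis and cytoskeleton list had 2 of 14 (Pgk and Tpi, both glycolytic; adjusted p = 0.146, Fisher's exact test). The cell cycle list had 1 of 14 (CycB, cyclin B), the neuronal markers 1 of 12 (elav), the muscle markers 1 of 12 (Mef2), proteasome genes 1 of 48, ribosomal protein genes 2 of 85 and tRNA genes 2 of 290. No site was found at 179 chemoreceptor genes (p = 0.0237, adjusted p = 0.135, Fisher's exact test), 111 genes of the histone repeat cluster (adjusted p = 0.286), 14 chromatin and insulator genes, 13 heat shock genes, 11 ecdysone response genes, 10 germline genes or 7 dosage compensation genes (adjusted p = 1 for each of these 5 lists). Without 6 U replicate 1 or replicate 2 the chemoreceptor list passed as lower (adjusted p = 0.0411 and 0.0438, Fisher's exact test). The histone and Hsp70 copies are nearly identical, so reads cannot be assigned to a copy with certainty and their values are uncertain. Single peaks were found in some libraries at these genes, such as Hsp70Ba in 15 of 17, Iswi (the nucleosome remodelling ATPase gene) in 9 and mle in 7.

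**Figure D3:**
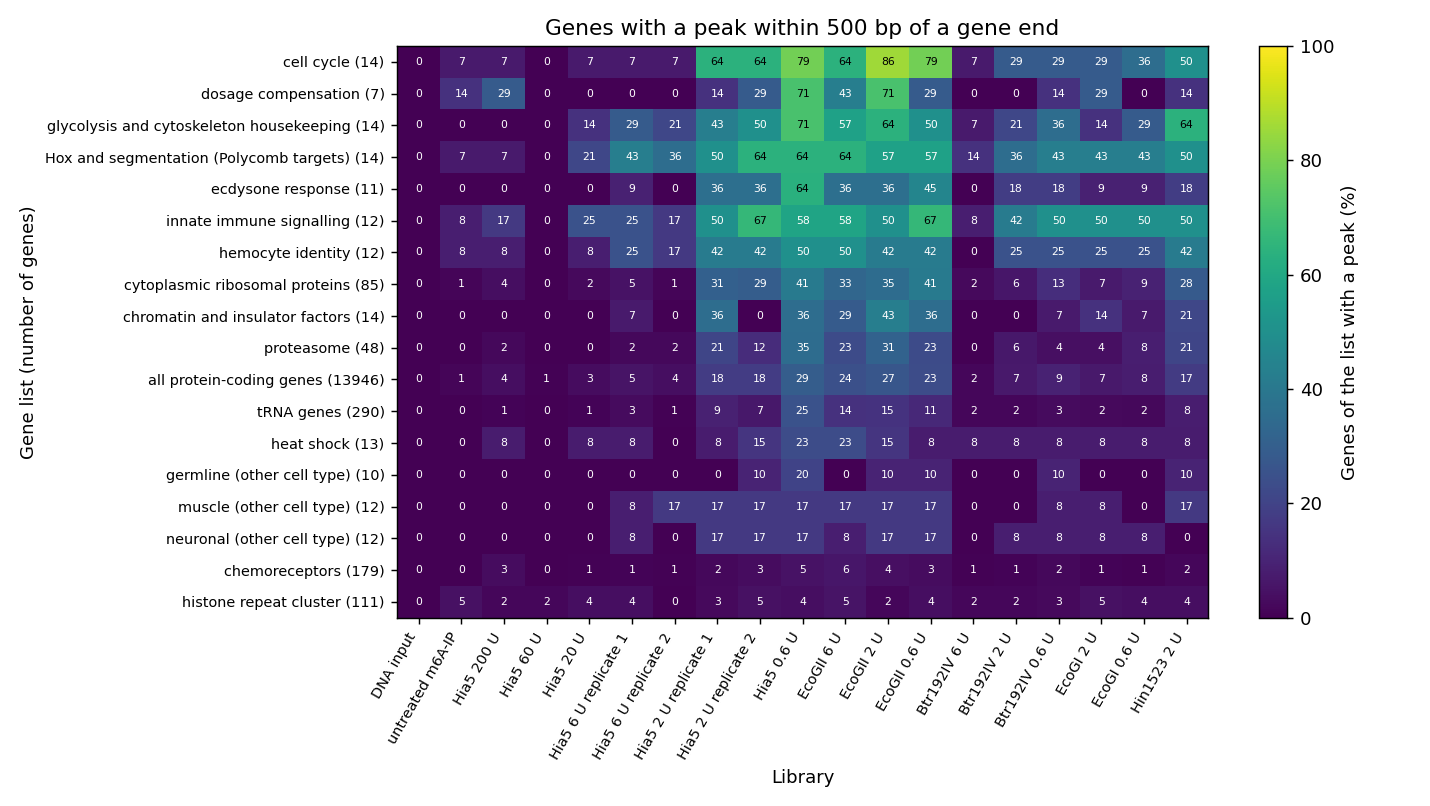
Percent of genes in each list (rows, number of genes in brackets) with a peak within 500 bp of a gene end, for each library (columns); the colour scale runs from 0 to 100%. The Hox and segmentation list stands at 64.3% in Hia5 0.6 U and 7.14% in Hia5 200 U, against 29.4% and 3.89% of all protein-coding genes.

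The number of genes marked by one enzyme and not by another ran from 0 to 136. A gene had to have a peak in all libraries of one side and none of the other. These numbers therefore depend on the lengths of the lists and on how many libraries each side held. Each count sets 1 enzyme against Hia5, so "alone" below leaves the further enzymes out of account. Gene-end peaks were present in all 3 EcoGII libraries and absent from all 5 Hia5 libraries at 0.6 to 6 U for 33 protein-coding genes, and the reverse held for 0. The 33 included borr (borealin-related, a chromosomal passenger protein), the neighbours CG34001 and hay (the TFIIH helicase), Irp-1B (an iron regulatory protein) and Krn (Keren, a ligand of the EGF receptor). Against Btr192IV, 7 genes were marked by Hia5 alone, among them Asx (Additional sex combs, a Polycomb-group gene), its neighbour Cpsf160, osp, lace (sphingolipid synthesis) and Men-b (a malic enzyme), and 4 by Btr192IV alone (CG17287, CG30458, CG32241 and CG5267). Against EcoGI, 14 genes were marked by Hia5 alone, among them Asx, Pdp1 (a clock transcription factor), CG33199, puml and mlt. CG5267 was the 1 gene marked by EcoGI alone. Over all enzymes, Pdp1 had a gene-end peak in 14 of 17 treated libraries, CG33199, puml and mlt in 11, Asx in 8 and CG5267 in 6. Against the single Hin1523 library 6 were marked by Hia5 alone, among them Asx, msi (musashi), Cpsf160, rdx and CG3061, and 136 by Hin1523 alone, led by CG10591, CG10283, CG12084, its neighbour hfp and CG2685.

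EcoGII held 6772, 7969 and 13395 peaks at 0.6, 2 and 6 U, and Btr192IV 3692, 3098 and 1425. EcoGI held 2916 at 0.6 U and 3012 at 2 U, and Hin1523 5546 at 2 U. The unit of one enzyme need not equal that of another. With doses pooled, the mean log2 number of peaks was 13.13 ± 0.51 in EcoGII (SD, n = 3) against 12.12 ± 0.81 in Hia5 (SD, n = 5), a difference of 1.02 that did not pass (exact two-sided permutation p = 0.143, adjusted p = 0.5). Btr192IV differed from Hia5 by -0.81 (exact permutation p = 0.214, adjusted p = 0.5) and EcoGI by -0.58 (exact permutation p = 0.429, adjusted p = 0.643). The gene-end share was 39.8% ± 9.56 in EcoGII, 29.6% ± 6.47 in Btr192IV and 35.6% ± 1.48 in EcoGI (SD, n = 3, 3 and 2), against 37.3% ± 8.88 in Hia5 (SD, n = 5). None of these differences passed (exact permutation, adjusted p = 0.814, 0.5 and 0.905), but doses were pooled here and the Hia5 mean includes 6 U, which EcoGI lacks. In the full lists, Btr192IV and EcoGI lay below the Hia5 mean in both measures at each shared dose. In lists of equal length the gene-end share at 0.6 U was higher in Btr192IV (33.03%) and EcoGI (32.9%) than in Hia5 (32.0%). At 2 U it was 30.05% in Btr192IV and 32.8% in EcoGI, against 34.5% and 31.2% in the Hia5 replicates. At 6 U it was 23.96% in Btr192IV, against 32.0% and 30.7% in Hia5. The lower share at 0.6 U was thus not seen at equal length. In a comparison of the full lists at shared doses, chosen after seeing the data, Btr192IV differed by -0.95 log2 units and -9.63 points (exact two-sided permutation within doses, p = 0.0556 each, adjusted p = 0.167). EcoGI differed by -1.22 log2 units and -8.98 points (exact permutation p = 0.167 each, adjusted p = 0.2), and EcoGII by 0.87 log2 units and 0.580 points (exact permutation p = 0.111 and 0.778). By dose, EcoGII differed by -0.255 log2 units at 0.6 U, 0.430 at 2 U and 2.44 at 6 U, so its mean rested largely on the 6 U library. Its gene-end share differed by -3.48, 4.87 and 0.350 points at these doses. The smallest p of the permutation within doses is 0.0556 with 3 shared doses and 0.167 with 2, so this permutation test cannot pass. No model-based test was run. With doses pooled the smallest p of the permutation test is 0.0179 for 3 libraries against 5 and 0.0476 for 2 against 5. These are values before adjustment. After adjustment over the 6 comparisons, 1 comparison alone at its smallest p cannot pass.

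Libraries of 1 enzyme were not more alike than libraries of different enzymes over all 17. The mean Jaccard index of covered bases was 0.205 within enzymes and 0.224 between them, a difference of -0.0190 (one-sided permutation p = 0.724). The closest pairs were Hia5 0.6 U with EcoGII 0.6 U (0.460), EcoGII 2 U with EcoGII 0.6 U (0.460), Hia5 0.6 U with EcoGII 2 U (0.445) and Hia5 2 U replicate 2 with Hin1523 2 U (0.431). The nearest library was of the same enzyme for 6 of the 16 libraries with another of their enzyme, and of the same dose for 6 of the 14 with another of their dose. The direction changed without the Hia5 doses above 6 U, which no other enzyme had. Over the 14 libraries at 0.6, 2 and 6 U the difference was 0.0192 (one-sided permutation p = 0.223). Over the 9 libraries of the other enzymes it was 0.0760 (exact one-sided permutation p = 0.0365), and within the second run 0.0349 (permutation p = 0.146, 12 libraries). The comparison over all 17 libraries therefore mixes enzyme with dose.

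**Figure D4:**
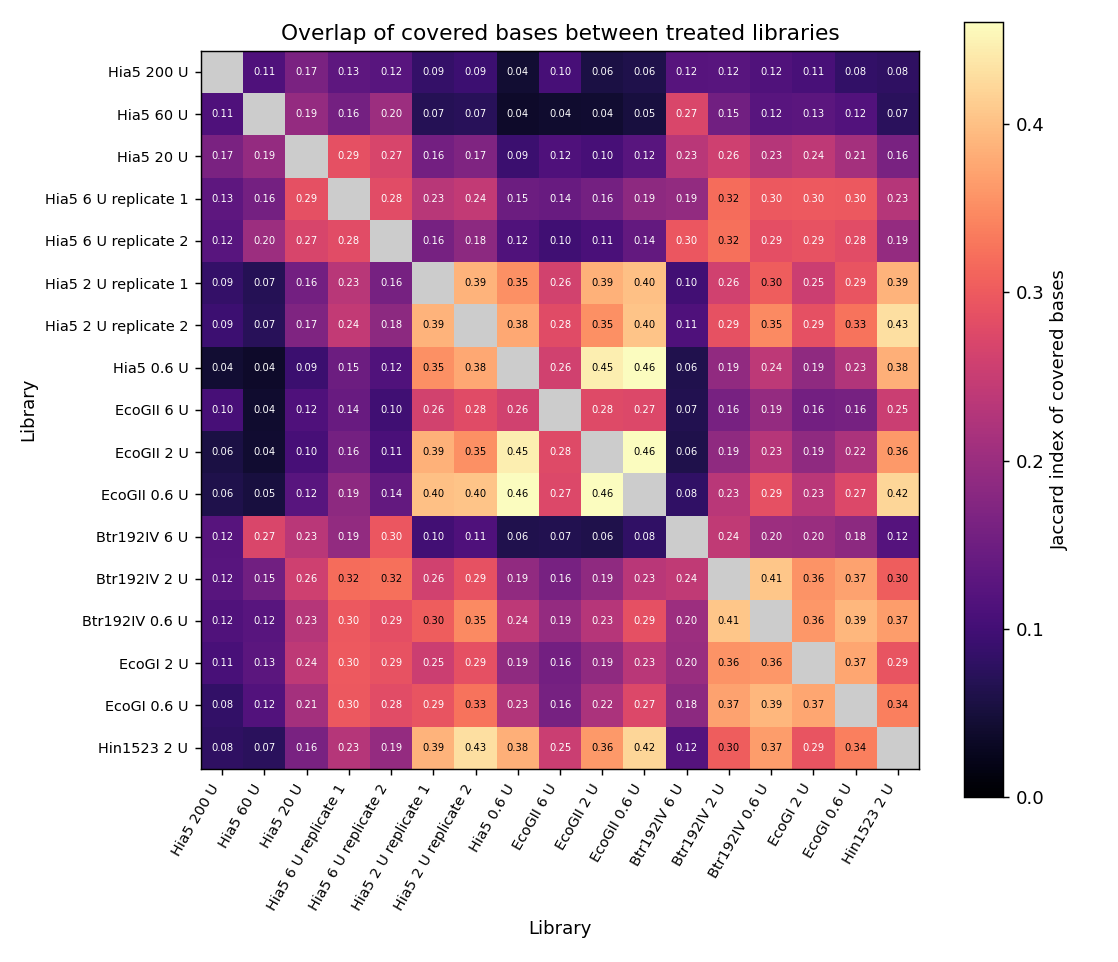
Jaccard index of covered bases for each pair of treated libraries (rows and columns), on a colour scale from 0. Hia5 0.6 U and EcoGII 0.6 U reach 0.46, and Hia5 60 U and Hia5 200 U are low against most libraries.

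Peaks were spread over all large chromosome arms. The density on X relative to the mean of 2L, 2R, 3L and 3R had a median of 0.857 over the treated libraries (0.644 at Hia5 200 U to 1.15 at Hia5 60 U) and was 0.817 in the untreated library. The input stood apart with a ratio of 9.72 (95% interval 4.38 to 23.1), from 21 peaks on X. Chromosome 4 held more peaks per Mb than X in some libraries and fewer in others. It had 26.5 against 12.1 on X in the untreated library, 31.1 against 13.3 at Hia5 20 U and 99.2 against 76.6 at EcoGII 6 U, but 41.7 against 58.2 at Hia5 0.6 U.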

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

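The tests of depth and of library runs for the dose trend, that of its 0.6 to 6 U part, both tests on EcoGII and that of chance spacing were chosen after the results were seen; those with lists of equal length or without dense runs used alternatives added after seeing the data.

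Peak numbers moved with dose in opposite directions in different enzymes. From 2 to 6 U the log2 number of peaks rose by 0.75 in EcoGII, and it fell by 0.99 and 1.53 in the Hia5 replicates and by 1.12 in Btr192IV. From 0.6 to 2 U it rose by 0.23 in EcoGII and by 0.047 in EcoGI, and fell by 0.51 and 0.39 in Hia5 and by 0.25 in Btr192IV. These differences between enzymes were not tested, since EcoGII, EcoGI and Btr192IV have 1 library per dose. The Hia5 fall of 1.53 set a library of relative depth 7.89 against one of 11.8, while that of 0.99 set 11.9 against 12.1. Each rise set a deeper library against a shallower one, so depth and dose cannot be told apart there. Relative depth was 9.89, 11.4 and 25.5 in EcoGII at 0.6, 2 and 6 U, and 7.77 and 9.28 in EcoGI at 0.6 and 2 U. The EcoGI rise was from 2916 to 3012 peaks. In Btr192IV depth was 8.78, 8.71 and 7.41 at 0.6, 2 and 6 U. From 0.6 to 2 U Hia5 fell while depth went from 7.28 to 12.1 and 11.8.

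The list of EcoGII at 6 U held 13395 peaks, and that library was also 2.24 times as deep as the 2 U library. Its 8020 peaks without a 2 U counterpart had a median height percentile of 33.7 within the list, against 75.3 for the shared peaks; greater depth would give this, and so would any other cause that adds weak peaks. An earlier test, which set heights of both lists on 1 scale and was inconclusive, was replaced by these ranks after its result was seen, because heights hold only within a list. Outside dense runs the ratio of 6 U to 2 U peaks was 1.27, against 1.68 over all peaks, which lies between the bounds set for and against dense runs as the cause and leaves them open. Depth may account for the longer list, and an effect of the EcoGII dose itself stays open as untested.

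The gene-end share of Hia5 peaks fell with dose, and several technical causes of the whole trend are argued against. Given relative depth the partial correlation was -0.945, within library runs the share fell at 6 of 6 dose steps, and r was -0.888 in lists of equal length and -0.954 without dense runs. The part from 0.6 to 6 U is different: in lists of equal length the 0.6 U share exceeded the 6 U mean by 0.648 percentage points, against 20.5 in the full lists, so that part may follow from the length of the lists. From 20 to 200 U the share still went from 29.0% to 19.04% in lists of equal length. If the dose itself sets how many peaks are called, equal lengths remove part of a dose effect, so methylation beyond open chromatin at high dose remains an untested hypothesis.

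Many peaks lay in dense runs that were present in some libraries and missing from others. In examples chosen after their values were seen, on 3L from 8407541 to 8421240, across Oseg1, Exo70, mtrm and CG32354, Hia5 200 U had 22 peaks, 0.6 U had 1 and the other libraries had 0; on 2R from 5243083 to 5264060, at Nipped-A and d4, the untreated library had 36, Hia5 2 U replicate 1 had 36, the 3 EcoGII libraries had 37 to 41 and Hia5 2 U replicate 2 had 0. Chance spacing is argued against, with 135 runs at Hia5 200 U against at most 1 in random placements. Deeper libraries had a larger percent of their peaks in runs (r = 0.804, two-sided permutation p = 0.00023, and rho = 0.767, permutation p = 0.00061, over 17 libraries; r = 0.691, p = 0.00208, without EcoGII 6 U and Hia5 200 U; r = 0.959, p = 0.00023, and rho = 0.769, p = 0.00467, in the 12 libraries of the second run), so depth is a candidate explanation, while broad weak signal stays open: the median height percentile in runs was 18.8 in Hia5 6 U replicate 1 and 74.2 in Btr192IV 6 U, with a median over libraries of 40.01. No biological explanation was tested.

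For the genes that separated EcoGII or Btr192IV from Hia5, chance cannot be excluded; EcoGI and Hin1523 were not put to this test. Against Hia5, EcoGII gave 33 genes in both directions, but 12 of the 56 splits of the 8 libraries gave as many, the highest other split 242 (Hia5 0.6 U with EcoGII 2 U and 0.6 U). Btr192IV gave 11 genes, and 10 of 56 splits gave as many, the highest other split 497 (Hia5 0.6 U with both 2 U replicates). The highest splits hold several times the real counts and join libraries with long lists, which points to a structure of the samples other than the enzyme.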

How the results depend on the processing

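Results without dense runs, comparisons of enzymes at shared doses, those of the dose trend and of gene-end shares in lists of equal length, and gene lists set against Hia5 2 U sites or 0.6 U peaks came from alternatives chosen after seeing the data.

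For the main results, 178 values under alternatives stayed the same, 18 moved, 8 reversed and 5 newly passed. For a test, the same means the same direction and side of the threshold. For a count or share without a test, it means within a set distance of the main value, and moved means beyond it. For single gene lists and other details 155 stayed, 18 reversed, 12 newly passed and 2 no longer passed. Hia5 6 U against 2 U, and the enzymes against Hia5 in the second run or at shared doses, cannot pass the permutation tests used, so their p-values say nothing about stability. Where values changed, the cause was not tested, except where fewer peaks or stricter overlap lower a count by construction. The gene-end share of Hia5 peaks fell with dose in each setting run, with r from -0.971 to -0.923 when single libraries were left out. For the number of peaks r ran from -0.947 (without 200 U) to -0.487 (without 0.6 U), and for overlap with untreated peaks from 0.521 to 0.955. Without dense runs these correlations were -0.754 and 0.704, and in lists of equal length the second was 0.916; all 3 passed. With only the higher peaks of each list, those above its median height, the median list had 1846 peaks over 378 kb, and replicates shared 71.5% (2 U) and 60.2% (6 U) of peaks. They shared 45.1% and 37.8% at 50% reciprocal overlap, 54.1% and 47.8% by midpoints within 75 bp, and 48.8% at 6 U without control peaks. Reproducible sites numbered 1054 to 1665 when 1 of the 4 libraries was left out (1665 without 6 U replicate 2), and 241 in all 8 Hia5 libraries.

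The similarity of libraries within enzymes minus that between enzymes turned positive at 0.6, 2 and 6 U (0.0192), in the second run (0.0349) and without Hia5 (0.0760). The gene-end share of EcoGII minus Hia5 ran from -0.285 (without EcoGII 0.6 U) to 8.03 points (without EcoGII 6 U), was -0.213 without EcoGII 2 U and -0.294 in lists of equal length. For EcoGI minus Hia5 it ran from -4.06 (without Hia5 6 U replicate 2) to 1.25 (without Hia5 0.6 U), and was 0.764 in lists of equal length. For Btr192IV minus Hia5 it was -7.70 points in the full lists and -3.06 in lists of equal length.

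The Hox and segmentation list passed in each setting run, with adjusted p from 3.45e-05 to 0.0220 (Fisher's exact test). The hemocyte list was lost with windows of 200 bp and at 0.6 U (adjusted p = 0.0686 and 0.202, Fisher's exact test), which left 1 higher list at 200 bp. Leaving out a library gave 2 higher and 0 to 1 lower lists; the 1 lower list, seen when either 6 U replicate was left out, was the chemoreceptors. Sites of both 2 U replicates gave 4 higher and 3 lower lists, and 0.6 U peaks 6 higher and 2 lower ones. Differences from other genes, in percentage points, turned positive without 6 U replicate 2 for heat shock (3.43), ribosomal protein (1.63) and ecdysone genes (4.83); their lowest values with a library left out were -3.09, -0.742 and -3.09. With 2 U sites they turned for ribosomal protein (8.11) and ecdysone genes (15.3). With 0.6 U peaks they turned for ribosomal protein (12.2), proteasome (6.43), chromatin (6.71), dosage compensation (44.5) and ecdysone genes (34.7), and to -12.4 for neuronal and for muscle genes. Windows of 200 bp turned proteasome genes to 0.443 and cell cycle and neuronal genes to -1.64 each, and ribosomal protein genes stood at 0.146 with 1000 bp, 0.0587 without dense runs and 0.0579 against matched genes.

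With the replicate number as a replicate block, Hia5 6 U minus 2 U stayed at -1.26 log2 units and at -11.97 points (exact sign-flip permutation p = 0.5 each, the smallest that 2 pairs allow). Deviations of same-numbered libraries correlated at r = 0.0228 over 1379 bins of 100 kb, so the numbers are not taken to pair libraries, and they follow the library run. Leaving out 1 replicate gave -1.47 to -1.05 log2 units and -13.3 to -10.7 points. Motifs, GC content and the 5' ends of all transcripts were not run, and correlations with dose within a library run were left out because each run holds fewer than 6 Hia5 libraries. Relative depth differed between libraries and read totals are not given in the sources used here, so a missing peak in a shallow library does not show missing methylation.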

Other observations

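The gene lists at Hia5 2 U and 0.6 U, the lists of equal length and the results without dense runs were chosen after seeing the data, as was the first comparison of doses over all 17 treated libraries.

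At the lowest Hia5 dose, peaks outside control peaks reached the ends of 4046 protein-coding genes. Cell cycle genes had such a peak in 11 of 14 cases (adjusted p = 0.000995, Fisher's exact test), against 29.0% of other protein-coding genes, with CycB, stg (the Cdc25 phosphatase string) and CycA among them. The glycolysis and cytoskeleton list had 10 of 14 (adjusted p = 0.00529, Fisher's exact test), Hox and segmentation genes 9 of 14 (adjusted p = 0.0220), ribosomal protein genes 35 of 85, dosage compensation genes 5 of 7 and ecdysone response genes 7 of 11 (adjusted p = 0.0382 each). Chemoreceptor genes had 9 of 179 (adjusted p = 3.00e-15) and genes of the histone repeat cluster 0 of 111 (adjusted p = 5.5e-16, Fisher's exact test each), both lower than other genes. The histone copies are nearly identical and lie in a single cluster, so they are not independent genes and their p overstates the evidence. With peaks that overlap control peaks kept, 4 of 111 had a peak at Hia5 0.6 U, and 5 of 111 had one in the untreated library. Among markers of other cell types, neuronal and muscle genes had 2 of 12 each and germline genes 2 of 10, and none of these 3 lists passed the test.

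In sites of both 2 U replicates the lists that were higher were cell cycle (6 of 14, adjusted p = 0.0125), Hox and segmentation (7 of 14, adjusted p = 0.00232), hemocyte and innate immune genes (5 of 12 and adjusted p = 0.0225 each, Fisher's exact test). Lower lists were chemoreceptors (4 of 179, adjusted p = 3.25e-05), the histone repeat cluster (0 of 111, adjusted p = 1.85e-05) and tRNA genes (13 of 290, adjusted p = 0.000992, Fisher's exact test). Windows at both ends of a short gene overlap, so tRNA genes cover fewer bases and a lower share is partly built in. Histone copies lie in a single cluster and are not independent genes, so their p overstates the evidence. Over all treated libraries, 25 protein-coding genes had a gene-end peak in 17 of 17 and 7900 had none in any.

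Libraries treated at 1 dose, whatever the enzyme, may share more sites than libraries of different doses. This was first noticed over all 17 treated libraries, where the mean Jaccard index was 0.284 within doses and 0.203 between them, a difference of 0.0808 (one-sided permutation p = 0.00374; 0.108 with p = 0.00147 in lists of equal length). Since 20, 60 and 200 U were used with Hia5 alone and lie far from the others, the hypothesis was then tested at 0.6, 2 and 6 U, where the difference was 0.0318 (permutation p = 0.0799). In lists of equal length it was 0.0338 (permutation p = 0.0561), in the second run 0.0306 (permutation p = 0.115, 12 libraries) and without dense runs 0.0277 (permutation p = 0.104). The size thus stayed when lengths were made equal but missed the threshold, and same-dose pairs include the Hia5 replicates, so the question stays open.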
